A study of Mus musculus with 12 samples.

How the data were processed

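RNA from the jejunal epithelium of mice was measured on 12 Affymetrix 430 2.0 arrays, 4 from littermate controls, 3 labelled Cdx2 knockout, 2 labelled Hnf4a knockout and 3 labelled knockout of both genes. Mice of a mixed 129 and C57BL6 background received 1 mg of tamoxifen a day for 5 days to inactivate the gene or genes, and epithelium was taken 3 to 4 days later, per the labels' protocols. The epithelium was released with EDTA and RNA was extracted with Trizol, per the labels. Groups and replicate numbers were taken from the sample titles.

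The deposited values are on the log2 scale and were made by the authors with RMA, per the submitters' processing notes, which also name limma and give no version of either. They ran from 3.68 to 15.47, and the array medians lay between 7.79 and 7.86. Sorted values of any 2 arrays differed by at most 0.38 on the log2 scale, so the arrays shared nearly the same distribution without being identical, and whether all 12 were summarised together is not given in the sources used here. The deposited table held 22587 features, of which 64 were Affymetrix control features and 22523 carried RefSeq accessions, so probes had been regrouped by transcript with a definition that is not given in the sources used here. Of the latter, 18294 matched exactly 1 symbol in a RefSeq gene table of the assembly GRCm38.p6, which served for names only. The remaining 4229 matched none or more than 1 and were left without a symbol. The matched features covered 15653 symbols. Among the RefSeq features, 7328 had the same values as another one, leaving 18172 distinct sets of values. The feature with the highest mean over the arrays stood for a gene. A feature was kept where it exceeded the 30th percentile of its array in at least 2 arrays, which removed 4445 named features. This left 11817 genes to test, and 17 tested features that stand for several symbols were never named.

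The values of all 12 arrays were fitted in limma 3.58.1 under R 4.3.3 with a mean per group, lmFit and eBayes, and the Benjamini-Hochberg adjustment over all genes tested. The fit had 8 residual degrees of freedom and a prior worth 2.94. A gene was called at an adjusted p under 0.05. The 6 contrasts were each knockout group against the controls, the double knockout against either single knockout, and the interaction, which is the difference between the effect of Cdx2 loss with Hnf4a lost and its effect with Hnf4a present. The deposited values carry no detection calls, so a level in the lower range of an array is not shown to lie above background, and differences from such levels are differences of signals. All log2 differences in the text are from this fit, with their standard error (SE), and adjusted p-values of genes are from it too. Figures were drawn with matplotlib 3.10.9. Nothing in the labels says that the arrays of a group came from separate animals, so p-values measure only the spread between these arrays, which may be technical. The number of arrays limits the precision of every value. On simulated data with the same genes and group sizes, the test recovered 84.5% of genes changed by 1 on the log2 scale for the Cdx2 knockout, 78.7% for the Hnf4a knockout and 83.7% for the double knockout. False genes made up 6.37%, 5.37% and 6.23% of the calls in these simulations. Simulated values varied independently between genes and held no effect of origin or pairing, so these shares need not hold for the real calls.

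Before the data were examined, 25 lists of genes were fixed, holding 461 symbols. They covered brush border and digestive enzymes, lipid absorption, sugar, amino acid and peptide transport, mineral and vitamin uptake, gastric genes, ileal and colonic genes, crypt and stem cell genes, cell cycle, fatty acid oxidation, cholesterol synthesis, xenobiotic metabolism, intestinal transcription factors, endoplasmic reticulum stress, antimicrobial and MHC class II genes, and interferon response. Others held markers of goblet, Paneth, enteroendocrine, tuft, T, B and plasma, myeloid, stromal and pancreatic acinar cells. Of all list members, 421 were on the array and 381 were tested; the list of red blood cell markers was left out for lack of tested members. Each of the 24 remaining lists was tested with limma's camera at a preset correlation of 0.01, adjusted over the lists within a contrast, and again with an estimated correlation and with fry. Camera sets the members of a list against the other genes, and fry tests them against no change. List p-values in the text are those of camera at the preset correlation unless another test is named.

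The genes named were fixed by a rule set beforehand. It takes the 8 called genes with the largest log2 difference of at least 1 in each direction for each group against the controls, with no overlap between the arrays of the groups compared, and 5 in each direction for the other contrasts. It adds up to 4 members of each list with the largest absolute difference in a contrast, the targeted genes, and any member of the list of intestinal transcription factors. A gene named outside the rule is said to have been chosen after its values were seen.

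Description labels gave the arrays 3 origins. Controls 1 to 3 and the arrays labelled Cdx2 knockout shared an origin, and control 4 had its own. The Hnf4a and double knockout arrays were taken to share the remaining origin, since their descriptions name scans and no earlier series. Origin and genotype therefore cannot be told apart where the Hnf4a or double knockout is set against the controls, or the double against the Cdx2 knockout. Same-numbered arrays labelled control and Cdx2 knockout deviated together, with correlations over genes of 0.34, 0.16 and 0.61 for numbers 1, 2 and 3. Control 1 correlated slightly better with Cdx2 knockout 2 (0.36) than with its own number, so the check is weak for numbers 1 and 2. The numbers were still taken to pair these arrays. The pairing comes from the titles' numbers and this check, not from a stated litter or day. For the other groups the numbers were not taken to pair arrays.

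Alternatives covered the filter, the choice of feature per gene, renormalization, array weights, a trended and robust spread, the samples in the fit, the origin as a block, the replicate number as a block, control 4 left out or alone, stricter thresholds, and each array left out in turn. For the labelled Cdx2 knockout against control and for the interaction, the origin as a fixed block gives the same values as leaving out control 4. Those added after the data were examined were the 6 arrays of 1 origin alone, the same with the replicate number as a block, and a fit without the 4 arrays of highest 18S ribosomal RNA signal. Control features for the 3' and 5' ends of actin and Gapdh and for 18S ribosomal RNA were used for quality only. Results of single genes withheld for evaluation are not reported here.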

Results

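The arrays measured transcript levels in jejunal epithelium, the nutrient-absorbing lining of the middle small intestine, after tamoxifen-induced loss of Cdx2, of Hnf4a or of both. Cdx2 is a homeobox transcription factor of the intestinal epithelium and Hnf4a a nuclear receptor of liver and gut. The question posed by the design is what each factor alone, and both together, maintain in the adult epithelium. There were 4 control arrays, 3 labelled Cdx2 knockout, 2 labelled Hnf4a knockout and 3 labelled double knockout. Replicate arrays correlated over genes at 0.945 to 0.980 within the controls, 0.960 to 0.977 within the Cdx2 group, 0.986 for the Hnf4a pair and 0.974 to 0.982 within the double knockout. Signal of 18S ribosomal RNA, a sign of how RNA was prepared, averaged 7.93 ± 0.18 (SD, n = 4) in the controls, 8.98 ± 1.45 (n = 3) in the Cdx2 group, 9.11 ± 0.26 (n = 2) in the Hnf4a group and 8.58 ± 1.30 (n = 3) in the double knockout.

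The targeted genes were read first in every array. Hnf4a signal was 12.44, 12.40, 12.49 and 12.39 in the controls, 10.48 and 10.78 in the Hnf4a knockout, and 10.16, 10.02 and 10.25 in the double knockout, a difference from the control mean of -1.80 ± 0.14 (SE, adjusted p = 0.0002) and -2.29 ± 0.12 (adjusted p = 6.2e-07). It was also lower in the arrays labelled Cdx2 knockout, at 11.81, 11.46 and 11.98 (-0.68 ± 0.12, adjusted p = 0.0049). Cdx2 signal went against the label. It was 10.20, 9.69, 9.99 and 9.96 in the controls and 10.99, 10.10 and 10.83 in the arrays labelled Cdx2 knockout (0.68 ± 0.21, adjusted p = 0.056, and adjusted p = 0.0294 with the replicate number as a block). In the arrays labelled double knockout it reached 11.41, 11.65 and 11.95 (1.71 ± 0.21, adjusted p = 0.00017), and in the Hnf4a knockout 11.13 and 11.11 (1.16, adjusted p = 0.06). Where the probes lie relative to the deleted part of Cdx2 is not given in the sources used here, so this signal cannot check the label, and every direction given for Cdx2 loss rests on the labels.

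**Figure D1:**
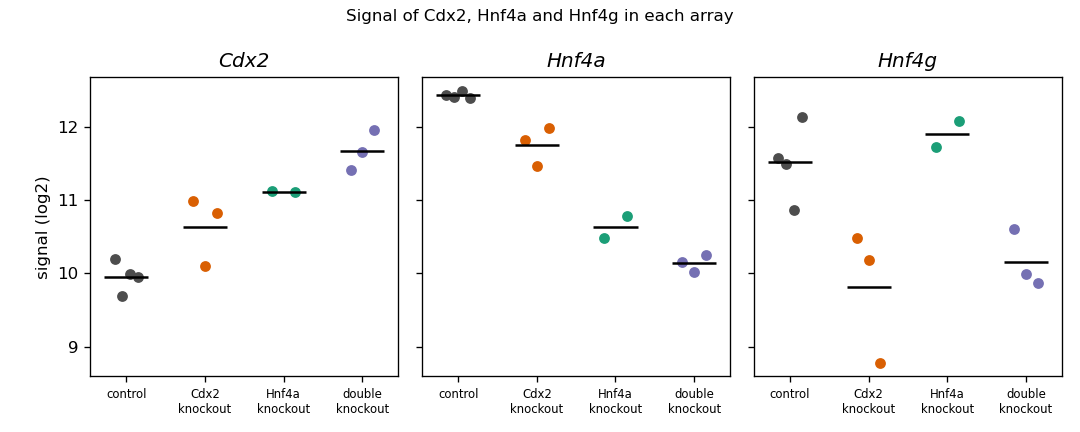
Log2 signal of Cdx2, Hnf4a and the related receptor Hnf4g in each array, grouped by label, with lines at the group means. Hnf4a lies between 12.39 and 12.49 in the controls and at 10.78 or below where it was targeted, while Cdx2 lies higher in the arrays labelled Cdx2 knockout (10.10 to 10.99) than its mean in the controls.

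Loss of Cdx2 alone was read from the 3 arrays labelled Cdx2 knockout against the 4 controls. Gastric genes rose and several genes of the absorptive enterocyte fell. Transthyretin (Ttr), a carrier of thyroid hormone and of retinol-binding protein, went from 7.18 ± 0.17 (SD, n = 4) to 14.16 ± 0.16 (n = 3), a 127-fold rise (log2 difference 6.98 ± 0.15 SE, adjusted p = 5.8e-10). The sulfotransferase Sult1c2 rose by 5.56 ± 0.17 (adjusted p = 9.8e-09), the hyaluronan receptor Lyve1 by 5.54 ± 0.29, and Gml2, Cyp2d10 and Ly6d by 5.27, 5.23 and 5.19. Large falls were those of the nuclease Dnase1 (-6.09 ± 0.17, adjusted p = 5.2e-09), the secreted lectin Reg3a (-5.39 ± 0.28), Gsdmc2 (-5.19 ± 0.70), the membrane carbonic anhydrase Car4 (-4.84 ± 0.70) and Tmigd1 (-4.67 ± 0.34). Bcl2l15, the sulfate cotransporter Slc13a1 and the efflux pump Abcb1a also fell (-4.58, -4.53 and -4.49). Control levels of Sult1c2 (6.66), Lyve1 (6.60), Gml2 (6.17) and Cyp2d10 (5.21) lay below the 30th percentile of the arrays (6.75) and are not shown to exceed background. The same holds in the Cdx2 group for Dnase1 (6.62), Reg3a (6.56), Gsdmc2 (4.93), Tmigd1 (5.35), Bcl2l15 (6.35) and Slc13a1.

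Of the 16 tested gastric genes, 9 rose and 7 did not pass, with 10 rising when adjusted over the list alone (median 1.37, adjusted p = 3.6e-07, and adjusted p = 0.009 with an estimated correlation). They included Anxa10 (3.45 ± 0.53) and the gastrokines Gkn3 (3.07 ± 0.22), Gkn2 (3.02 ± 0.46) and Gkn1 (2.98 ± 0.50), secreted proteins of the stomach surface. The control level of Gkn1 (6.64) also lay below the 30th percentile (6.75) and is not shown to exceed background. The list lay 1.36, 1.63 and 1.29 above the control mean in the 3 arrays. Among 23 brush border and digestive enzyme genes, 8 fell and 15 did not pass, and 12 fell adjusted over the list alone (median -0.45, adjusted p = 0.00017, but adjusted p = 0.58 with an estimated correlation). Pdzk1, a scaffold of apical transporters, fell (-4.19 ± 0.40), and so did lactase (Lct, -3.55 ± 0.38). Enteroendocrine markers fell in 12 of 18 cases, 13 adjusted over the list alone (median -1.04, adjusted p = 2.4e-08, and adjusted p = 0.18 with an estimated correlation). The peptide hormone genes Nts, Gip and Tac1 changed by -3.33 ± 0.41, -2.11 ± 0.31 and -1.54 ± 0.19.

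Cholesterol synthesis genes rose in 15 of 20 cases. Adjusted over the list alone 17 rose and 1 fell (median 0.93, adjusted p = 2.6e-12, and adjusted p = 0.13 with an estimated correlation). The pathway enzymes Fdft1, Msmo1, Sqle and Cyp51 rose by 1.67 ± 0.22, 1.57 ± 0.21, 1.56 ± 0.20 and 1.55 ± 0.18. Of 11 tuft cell markers, 6 rose and 9 did so adjusted over the list alone (median 1.24, adjusted p = 4.5e-05, but adjusted p = 0.48 with an estimated correlation). The controls themselves spread from -0.55 to 0.70 around their mean for this list, against 0.49 to 1.91 in the Cdx2 group. Interferon response genes rose in 6 of 18 cases, 10 adjusted over the list alone (median 1.10, adjusted p = 5.2e-05, but adjusted p = 0.58 with an estimated correlation), with Usp18 up 2.30 ± 0.41 and Rsad2 up 2.19 ± 0.39. The list stood highest, at 1.69, in Cdx2 knockout 3, the array with the highest 18S signal (10.64), and at 0.90 and 0.66 in the other Cdx2 knockout arrays.

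Antimicrobial and MHC class II genes fell in 3 of 16 cases, and adjusted over the list alone 4 fell and 1 rose (median -0.77, adjusted p = 0.0045, and adjusted p = 0.13 with an estimated correlation). Endoplasmic reticulum stress genes fell in 3 of 22 cases, and adjusted over the list alone 4 fell and 1 rose (median -0.34, adjusted p = 0.0045, but adjusted p = 0.48 with an estimated correlation). Among 20 xenobiotic metabolism genes 5 rose and 3 fell, 7 and 3 adjusted over the list alone (median 0.48, adjusted p = 0.015, but adjusted p = 0.70 with an estimated correlation). The glutathione transferases Gsta4 and Gstm1 rose by 4.25 ± 0.22 and 2.42 ± 0.30. That list was no longer called without control 3 (adjusted p = 0.0964) or Cdx2 knockout 1 (0.164). Of 32 cell cycle genes 0 passed in limma by either adjustment and 7 were lower at an unadjusted p of 0.05, while the list as a whole stood lower (median -0.61, adjusted p = 0.00019, but adjusted p = 0.70 with an estimated correlation and 0.24 by fry). The median of the cell cycle list was -0.33 without control 3 and -0.35 without Cdx2 knockout 2, and that of the xenobiotic list 0.74 without Cdx2 knockout 3.

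Camera called none of the other lists over all arrays, and several held changes in both directions. Lipid absorption genes split into 4 that rose and 4 that fell of 22, by either adjustment, with a median of -0.14 and a mean of 0.12. The carotene-cleaving enzyme Bco1 rose by 4.63 ± 0.67 and the lipoprotein receptor Scarb1 by 3.46 ± 0.19, while the sterol transporter Abcg5 fell (-1.44 ± 0.15). Isx, a homeobox factor known to repress Bco1 and Scarb1, fell (-3.15 ± 0.13, adjusted p = 1.6e-07). In the list of 23 intestinal transcription factors 4 rose and 5 fell, 6 and 6 adjusted over the list alone, among them the vitamin D receptor Vdr (-1.62 ± 0.13), Foxa1 (1.09 ± 0.18) and Hnf4g (-1.71 ± 0.39, adjusted p = 0.0165). Over the 6 arrays of 1 origin Hnf4g was -1.50, with adjusted p = 0.126 without a block and 0.0129 with the replicate number as a block. Fry called the transcription factor list lower (adjusted p = 0.00173, with a median of -0.01 and a mean of -0.18). The list holds the targeted genes Cdx2 and Hnf4a, and Hnf4a is among those that fell. Mineral and vitamin uptake genes rose in 4 and fell in 6 of 16 cases, by either adjustment. The intracellular calcium carrier S100g rose by 4.83 ± 0.83 and Amn, a partner of the vitamin B12 receptor, fell (-1.49 ± 0.18). Of 14 sugar, amino acid and peptide transport genes 2 rose and 3 fell, by either adjustment, with Slc5a4a at -3.23 ± 0.53, Slc1a1 at -2.16 ± 0.23 and Slc36a1 at -2.15 ± 0.20. That list was not called (median -0.29, adjusted p = 0.157) but was without control 4 (-0.48, adjusted p = 0.00458) and with the replicate number as a block, a fit that gives control 4 no weight (-0.48, adjusted p = 0.00498). It was -0.08 (adjusted p = 0.336) without the 4 arrays of highest 18S signal. Fatty acid oxidation and ketogenesis genes rose in 6 and fell in 2 of 20 cases, 7 and 2 adjusted over the list alone, and camera called that list higher without control 1 (adjusted p = 0.0228) or Cdx2 knockout 3 (0.00874). Pdk4, a kinase that restrains glucose oxidation, rose by 5.04 ± 0.73, and the coactivator Ppargc1a fell (-2.12 ± 0.34).

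In the list of 13 ileal and colonic genes 2 rose and 4 fell, 3 and 5 adjusted over the list alone, with the water channel Aqp4 up 1.98 ± 0.34 and the bile acid exporter subunit Slc51a at -1.85 ± 0.29. Goblet cell markers fell in 1 of 12 cases and crypt and stem cell genes in 1 of 17, with the same counts adjusted over the list alone. Few markers of other cell types passed. In limma's test 0 of 6 Paneth, 0 of 12 T cell, 0 of 5 B and plasma cell, 0 of 7 stromal and 0 of 6 pancreatic acinar markers were called, also adjusted over the list alone, against 2, 0, 1, 1 and 2 at an unadjusted p of 0.05. Among 12 myeloid markers 1 rose by either adjustment (Mrc1, 1.15 ± 0.22). Camera called none of these lists over all arrays, and fry called the stromal list (higher, adjusted p = 0.0421). Without the 4 arrays of highest 18S signal camera called the myeloid list higher (median 0.27). The B and plasma cell list had a median of -0.15 and a mean of 0.16 over all arrays.

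In all, 1451 of 11817 genes were called, 763 higher and 688 lower, of which 503 differed at least 2-fold. Over the 6 arrays of 1 origin 708 were called, 370 higher and 338 lower, and without control 4, the only array of its origin, 1189; the gastric list held within that origin (median 1.36, adjusted p = 1.31e-07). Without the 4 arrays of highest 18S signal (Cdx2 knockout 3, Hnf4a knockout 1, double knockouts 2 and 3), 743 genes were called, 456 higher and 287 lower, and 56 of the 65 named calls were kept. With only the groups compared in the fit 955 were called, and with control 4 as the only control 619.

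**Figure D2:**
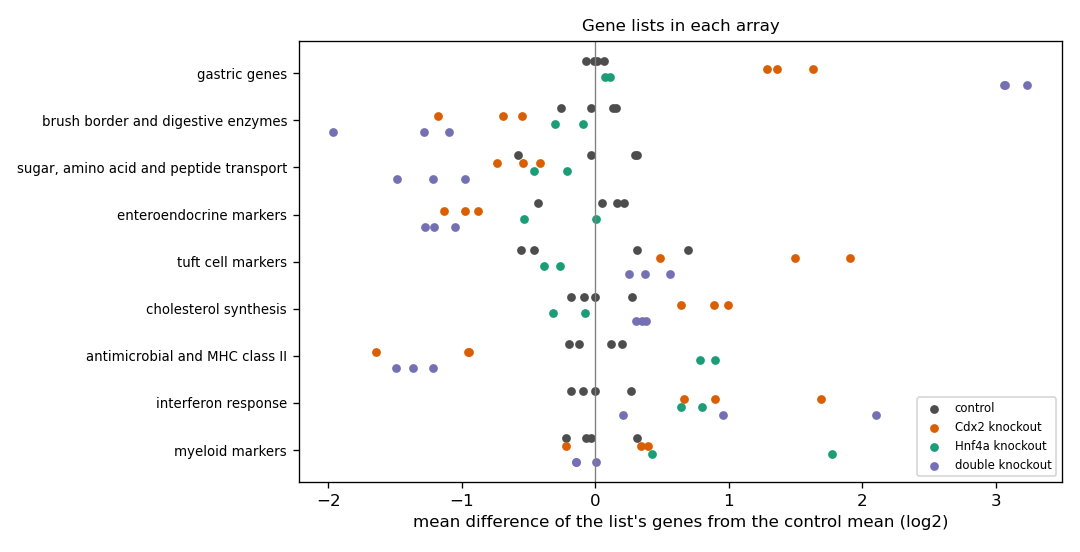
Mean log2 difference of a list's genes from the control mean, 1 point per array, for 9 lists. Gastric genes lie 1.29 to 1.63 above the control mean in the labelled Cdx2 knockout and 3.06 to 3.24 above it in the labelled double knockout, against 0.07 and 0.11 in the Hnf4a knockout.

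Loss of Hnf4a alone was read from 2 arrays against the 4 controls. Saa1, an acute-phase apolipoprotein, rose by 2.78 ± 0.18 (SE, adjusted p = 6.6e-05), the myosin light chain Myl7 by 2.10 ± 0.19 (adjusted p = 0.0006) and the serine protease Prss30 by 1.81 ± 0.18 (adjusted p = 0.0012). Saa1 averaged 5.53 in the controls, below the 30th percentile (6.75). Falls included those of LOC547349, an MHC class I-like gene (-3.37 ± 0.26, adjusted p = 0.0002) and the retinol dehydrogenase Rdh7 (-3.32 ± 0.22, adjusted p = 6.6e-05). Lrat, which makes retinyl esters, also fell (-1.88 ± 0.19, adjusted p = 0.0012). These calls and that of Hnf4a itself held whichever array was left out. Angptl4, an inhibitor of lipoprotein lipase, rose by 2.66 ± 0.35 (adjusted p = 0.0066), but not without Hnf4a knockout 1 (adjusted p = 0.144) or 2 (0.0575). Ada (-3.15 ± 0.56), Cyp2b10 (-2.96 ± 0.52) and Fbp1 (-2.22 ± 0.41) fell too, but each call was lost without any 1 of 9 arrays (adjusted p = 0.0502 to 0.431, 0.0508 to 0.242 and 0.0543 to 0.252). H2-Bl (-2.80 ± 0.32) and Adgrd1 (-1.88 ± 0.22) fell, and were not called without Hnf4a knockout 1 (adjusted p = 0.071 and 0.0988).

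Among the lists, 20 xenobiotic metabolism genes stood lower, with 1 that fell and 8 that fell adjusted over the list alone (median -0.69, adjusted p = 0.00019, but adjusted p = 0.51 with an estimated correlation). Lipid absorption genes also stood lower, with 1 of 22, Lrat, called by either adjustment (median -0.27, adjusted p = 0.0063, but adjusted p = 0.59 with an estimated correlation). Antimicrobial and MHC class II genes stood higher, with 1 of 16, Saa1, called by either adjustment (median 0.73, adjusted p = 0.00036, and adjusted p = 0.0913 with an estimated correlation). Goblet markers (median 0.34, adjusted p = 0.00088) and interferon response genes (median 0.55, adjusted p = 0.00036) stood higher and T cell markers lower (median -0.60, adjusted p = 1.3e-05), with 0 members called in limma by either adjustment and 4, 5 and 6 at an unadjusted p of 0.05. With an estimated correlation these became adjusted p = 0.51, 0.59 and 0.51. Myeloid markers stood higher (median 1.08, adjusted p = 2.4e-10, and adjusted p = 0.46 with an estimated correlation), with 1 of 12 called, Cd14 at 1.43 ± 0.22, and all 12 when adjusted over the list alone. The myeloid list lay 1.78 above the control mean in Hnf4a knockout 1 and 0.42 above it in Hnf4a knockout 2, against -0.22 to 0.31 in the controls, and Cd14 was not called without Hnf4a knockout 1 (adjusted p = 0.257). Without that array the medians were 0.36 for the myeloid, -0.37 for the xenobiotic and -0.13 for the lipid list, all still called, and without Hnf4a knockout 2 the myeloid median was 1.83. Gastric genes had a median of 0.08, with 0 of 16 called in limma by either adjustment and 1 at an unadjusted p of 0.05. Over all arrays camera called neither this list nor any list not given above. Without control 3 it also called cell cycle (median 0.46, adjusted p = 1.28e-05) and crypt genes (0.29, 0.00134) higher. It then called enteroendocrine (-0.37, 0.00107), fatty acid (-0.40, 0.00135), brush border (-0.16, 0.0445) and sugar transport genes (-0.29, 0.0445) lower. Some lists were also called without other single arrays, such as the sugar list without control 4 (-0.40, 0.000191).

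In all, 71 genes were called, 37 higher and 34 lower, 38 of them at least 2-fold, and 1546 passed an unadjusted p of 0.05. The count fell to 45 without control 1, 39 without control 2, 10 without Hnf4a knockout 1, 36 without Hnf4a knockout 2, and 46 and 38 without double knockouts 1 and 2, which share the estimate of the spread. It was 489 with array weights, 41 with only the groups compared in the fit and 25 with control 4 as the only control; origin and genotype cannot be told apart here. Signal of 18S RNA was 9.30 and 8.93 in these arrays against at most 8.18 in the controls, and without the 4 arrays of highest 18S signal, which leaves 1 Hnf4a knockout array assumed to vary like the other groups, 6 genes were called and 5 of 18 named calls were kept.

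Loss of both factors was read from 3 arrays labelled double knockout against the 4 controls. Genes of the stomach lining rose. Gkn1 went from 6.64, below the 30th percentile (6.75) and not shown to exceed background, to 13.94 (log2 difference 7.30 ± 0.50 SE, adjusted p = 3e-06), Gkn2 rose by 6.68 ± 0.46, the trefoil peptide Tff2 by 5.90 ± 0.25 (adjusted p = 1.3e-07) and the tight junction protein Cldn18 by 5.21 ± 0.25 (adjusted p = 2.4e-07). Ttr, Sult1c2, Ly6d and Lyve1 rose by 6.37, 5.93, 5.59 and 5.13. Dnase1 (-6.44 ± 0.17), Car4 (-6.14 ± 0.70), Reg3a (-5.19 ± 0.28), Bcl2l15 (-4.83 ± 0.26), LOC547349 (-4.72 ± 0.23) and Pmp22 (-4.64 ± 0.65) fell, as did the vitamin B12 receptor Cubn (-4.62 ± 0.47) and lactase (-4.61 ± 0.38).

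Gastric genes rose in 12 of 16 cases by either adjustment (median 2.83, adjusted p = 1.4e-10, and adjusted p = 0.0019 with an estimated correlation). Muc5ac, Atp4b, Barx1 and Chia1 did not pass, and were singled out after their values were seen; Muc5ac, a mucin of the stomach surface, was 7.59 in the controls and 7.76 in the double knockout. Brush border and digestive enzyme genes fell in 17 of 23 cases, 18 adjusted over the list alone (median -1.22, adjusted p = 6.7e-09, but adjusted p = 0.46 with an estimated correlation), with Pdzk1 at -4.49 ± 0.40, Enpep at -3.52 ± 0.43 and trehalase (Treh) at -3.44 ± 0.48. Sugar, amino acid and peptide transporters fell in 8 of 14 cases, 10 adjusted over the list alone (median -0.89, adjusted p = 5.7e-06, but adjusted p = 0.49 with an estimated correlation), with Slc5a4a at -3.61 ± 0.53 and Slc1a1 at -2.68 ± 0.23. Of 16 mineral and vitamin uptake genes 8 fell and 2 rose by either adjustment (median -0.84, adjusted p = 0.0022, but adjusted p = 0.49 with an estimated correlation), with Amn at -2.53 ± 0.18 and S100g at 3.56 ± 0.83. Lipid absorption genes fell in 10 and rose in 3 of 22 cases by either adjustment (median -0.33, adjusted p = 0.012, but adjusted p = 0.62 with an estimated correlation). Bco1 again rose (3.62 ± 0.67), as did Scarb1 (2.43 ± 0.19), and Lrat fell (-1.99 ± 0.17).

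**Figure D3:**
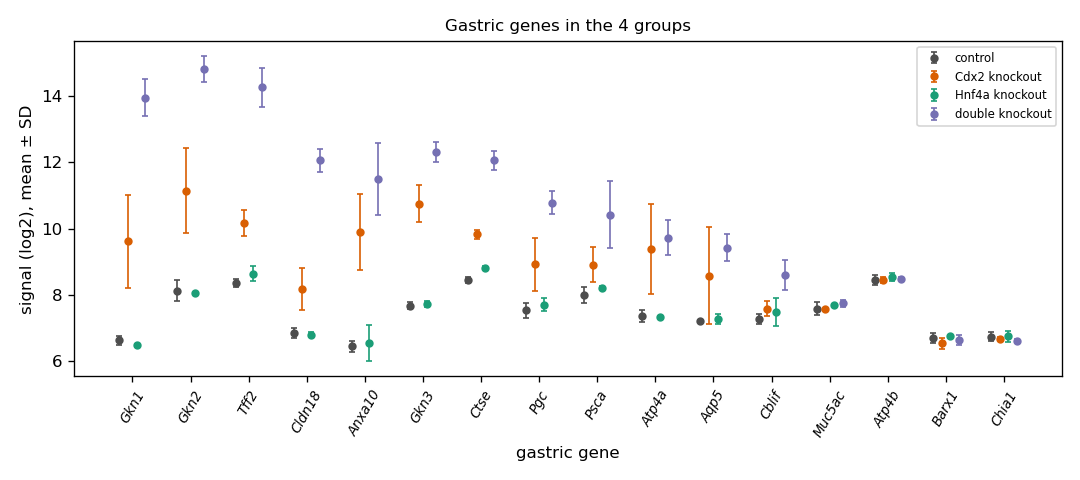
Mean log2 signal ± SD of the 16 tested gastric genes in the 4 groups (n = 4, 3, 2 and 3). Gkn1 averages 6.64 in the controls, 9.62 in the labelled Cdx2 knockout and 13.94 in the labelled double knockout, while Muc5ac lies between 7.57 and 7.76 in every group.

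Enteroendocrine markers fell in 12 of 18 cases, and adjusted over the list alone 12 fell and 1 rose (median -1.11, adjusted p = 3.4e-07, but adjusted p = 0.34 with an estimated correlation). Nts, Gip and the cholecystokinin gene Cck changed by -3.84 ± 0.41, -2.68 ± 0.31 and -2.28 ± 0.43. Cholesterol synthesis genes rose in 11 and fell in 2 of 20 cases, 12 and 3 adjusted over the list alone (median 0.47, adjusted p = 0.0041, but adjusted p = 0.62 with an estimated correlation), with Fdft1 up 1.09 ± 0.22. Interferon response genes rose in 10 of 18 cases, 11 adjusted over the list alone (median 1.13, adjusted p = 0.0011, but adjusted p = 0.62 with an estimated correlation). The list stood at 2.11, 0.21 and 0.96 in double knockouts 1, 2 and 3, whose 18S signals were 7.11, 9.02 and 9.61, and its median was 0.62 without double knockout 1. Antimicrobial and MHC class II genes fell in 5 of 16 cases by either adjustment (median -1.38, adjusted p = 0.0013, and adjusted p = 0.0778 with an estimated correlation), with a median of -0.89 without double knockout 3. Endoplasmic reticulum stress genes fell in 5 and rose in 1 of 22 cases by either adjustment (median -0.43, adjusted p = 0.0041, but adjusted p = 0.49 with an estimated correlation), with Edem1 at -0.90 ± 0.12. T cell markers stood lower with 0 of 12 members called in limma by either adjustment and 2 at an unadjusted p of 0.05 (median -0.38, adjusted p = 0.038, but adjusted p = 0.66 with an estimated correlation). This list was not called without control 3 (adjusted p = 0.144), control 4 (0.0932) or double knockout 3 (0.368). Without the 4 arrays of highest 18S signal the lipid, endoplasmic reticulum stress and T cell lists were not called (each with adjusted p = 0.0972).

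Of 12 goblet markers 5 rose and 1 fell by either adjustment, with the sensor Ern2 up 1.81 ± 0.18 and Creb3l1 up 1.66 ± 0.25, without a call for the list by camera (adjusted p = 0.067). Fry called the goblet list higher (adjusted p = 0.0445), and so did camera without the 4 arrays of highest 18S signal (median 0.77, adjusted p = 0.00148) and without any 1 of controls 1 and 2, Cdx2 knockouts 1 and 3 and double knockouts 2 and 3 (adjusted p from 0.0194 to just under 0.05). Crypt and stem cell genes rose in 4 and fell in 1 of 17 cases by either adjustment, among them Prom1 (1.35 ± 0.29) and Sox9 (0.83 ± 0.19). Among fits without 1 array, camera called that list higher without control 3 (adjusted p = 0.0113) or double knockout 1 (0.0378). Of 20 xenobiotic metabolism genes 4 rose and 8 fell, 5 and 8 adjusted over the list alone, with Gsta4 at 4.49 ± 0.22 and the efflux pumps Abcb1a and Abcg2 at -4.60 ± 0.65 and -2.11 ± 0.23. Fatty acid oxidation and ketogenesis genes rose in 6 and fell in 4 of 20 cases, 6 and 5 adjusted over the list alone, and had a median of -0.03 and a mean of 0.36; Pdk4 rose by 5.12 ± 0.73. Among 23 intestinal transcription factors 7 rose and 5 fell, 8 and 5 adjusted over the list alone, with Isx at -2.97 ± 0.13, Vdr at -2.05 ± 0.13 and Foxa1 at 1.87 ± 0.18. This list had a median of 0.25 and a mean of -0.02, was not called by camera and was called lower by fry (adjusted p = 0.0366). It holds both targeted genes, with Cdx2 among those that rose and Hnf4a among those that fell. The counts and fry's result therefore rest in part on the targeted genes themselves. In limma 0 of 11 tuft cell markers passed by either adjustment and 4 at an unadjusted p of 0.05 (median 0.29). Camera did not call the ileal and colonic list. The mean of its genes lay at -0.99, -1.15 and -0.91 from the control mean in double knockouts 1, 2 and 3. That mean includes Car4, whose large fall is given above, so it need not reflect most members. The controls spread from -0.70 to 0.82 for this list. The acinar marker Ctrb1, a chymotrypsinogen gene, rose by 3.46 ± 0.48, 1 of 2 members of 6 that passed by either adjustment, and fry, not camera, called that list higher (adjusted p = 0.0322).

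In all, 2804 genes were called, 1383 higher and 1421 lower, 847 of them at least 2-fold. Without the 4 arrays of highest 18S signal, which leaves 1 double knockout array assumed to vary like the other groups, 624 were called and 46 of 74 named calls were kept. With control 4 as the only control 1282 were called. Origin and genotype cannot be told apart in this contrast.

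The effect of Cdx2 loss where Hnf4a was also lost was read from the 3 labelled double knockout arrays against the 2 Hnf4a knockout arrays. Both groups were taken to share an origin. Ttr rose by 7.92 ± 0.18 (SE, adjusted p = 1e-09), Gkn1 by 7.46 ± 0.59, Gkn2 by 6.73 ± 0.55, Sult1c2 by 5.79 ± 0.20 and Tff2 by 5.61 ± 0.30. Dnase1 (-7.06 ± 0.20), Tmigd1 (-6.17 ± 0.40), Bcl2l15 (-5.95 ± 0.32), Reg3a (-5.73 ± 0.33) and Prss30 (-5.50 ± 0.19) fell. Gastric genes rose in 12 of 16 cases by either adjustment (median 2.72, adjusted p = 9.4e-12, and adjusted p = 0.0013 with an estimated correlation). Antimicrobial and MHC class II genes fell in 4 of 16 cases and in 12 adjusted over the list alone (median -2.49, adjusted p = 3.9e-08, and adjusted p = 0.0042 with an estimated correlation), with Saa1 at -3.47 ± 0.19. Myeloid markers fell in 4 of 12 cases, 11 adjusted over the list alone (median -1.27, adjusted p = 7.8e-06, but adjusted p = 0.29 with an estimated correlation). The myeloid median was -0.50 without Hnf4a knockout 1, whose list mean was 1.78, and -2.02 without Hnf4a knockout 2, whose list mean was 0.42, both still called. Ileal and colonic genes fell in 5 and rose in 1 of 13 cases, 6 and 2 adjusted over the list alone (median -1.40, adjusted p = 0.0091, but adjusted p = 0.26 with an estimated correlation). Both subunits of the bile acid exporter fell, Slc51b by 2.39 ± 0.32 and Slc51a further.

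Brush border genes fell in 14 of 23 cases here, 16 adjusted over the list alone (median -0.93, adjusted p = 1.3e-09, but adjusted p = 0.26 with an estimated correlation), and lactase changed by -4.34 ± 0.46. Sugar, amino acid and peptide transporters fell in 4 of 14 cases by either adjustment (median -0.70, adjusted p = 3.7e-05, but adjusted p = 0.30 with an estimated correlation). Mineral and vitamin uptake genes fell in 7 of 16, while adjusted over the list alone 9 fell and 1 rose (median -0.71, adjusted p = 7e-05, but adjusted p = 0.26 with an estimated correlation). For enteroendocrine markers 9 of 18 fell, and adjusted over the list alone 12 fell and 1 rose (median -0.87, adjusted p = 2.4e-06, but adjusted p = 0.26 with an estimated correlation). Cholesterol synthesis genes rose in 10 and fell in 1 of 20 cases, 12 and 1 adjusted over the list alone (median 0.70, adjusted p = 3.6e-05, but adjusted p = 0.29 with an estimated correlation). Endoplasmic reticulum stress genes fell in 3 of 22 by either adjustment (median -0.36, adjusted p = 0.00045, but adjusted p = 0.27 with an estimated correlation). Isx (-3.27 ± 0.15), Vdr (-2.12 ± 0.15), Bco1 (4.77 ± 0.80), Gsta4 (5.51 ± 0.26) and Gstm1 (4.07 ± 0.36) changed in the same direction as between the Cdx2 group and the controls. In all, 1286 genes were called, 654 higher and 632 lower, 616 at least 2-fold. The count was 854 without double knockout 3 and 3186 with array weights. It was lower too without either Hnf4a knockout array, which leaves 1 in that group. Without the 4 arrays of highest 18S signal only double knockout 1 and Hnf4a knockout 2 remain. That fit cannot tell an effect of 18S signal from the loss of replicates. All 55 named calls kept their direction in it.

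The effect of Hnf4a loss where Cdx2 was also lost was read from the 3 labelled double knockout arrays against the 3 labelled Cdx2 knockout. Gsdmc2 (4.94 ± 0.75 SE), Gkn1 (4.32 ± 0.53), Tff2 (4.09 ± 0.27, adjusted p = 2.3e-05), the membrane proteolipid Mal (3.97 ± 0.16, adjusted p = 6.1e-07) and the secreted protein Wfdc2 (3.96 ± 0.32) rose. The cytochrome Cyp1a1 (-4.38 ± 0.68), LOC547349 (-3.32 ± 0.25, adjusted p = 5.4e-05), the deiodinase Dio1 (-2.85 ± 0.42) and Tgfbi (-2.82 ± 0.42) fell. Gastric genes rose in 8 of 16 cases, 10 adjusted over the list alone (median 1.53, adjusted p = 4.7e-11, and adjusted p = 0.0016 with an estimated correlation). The xenobiotic list fell in 4 of 20 members, 8 adjusted over the list alone (median -0.53, adjusted p = 0.00046, but adjusted p = 0.37 with an estimated correlation), with the nuclear receptor Nr1i3 at -1.82 ± 0.22.

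Absorptive lists stood lower in this contrast, with more members passing over the list alone. Brush border genes fell in 2 of 23 cases and 17 adjusted over the list alone (median -0.65, adjusted p = 7.6e-08), and sugar, amino acid and peptide transporters in 3 of 14 and 6 adjusted over the list alone (median -0.63, adjusted p = 3e-06). Mineral and vitamin uptake genes fell in 3 of 16 and 9 adjusted over the list alone (median -0.67, adjusted p = 2e-05), and lipid absorption genes in 3 of 22 and 10 adjusted over the list alone (median -0.31, adjusted p = 2.1e-05). Each of these had adjusted p = 0.32 with an estimated correlation. Cholesterol synthesis genes fell in 3 of 20 cases, 10 adjusted over the list alone (median -0.47, adjusted p = 5.9e-08, but adjusted p = 0.32 with an estimated correlation). Cell cycle genes rose in 2 of 32, 12 adjusted over the list alone (median 0.81, adjusted p = 1.3e-06, but adjusted p = 0.45 with an estimated correlation). The mean of this list lay 0.11 to 0.26 above the control mean in the double knockout arrays, within the spread of the controls (-0.80 to 0.87). Goblet markers rose in 2 of 12, 3 adjusted over the list alone (median 0.44, adjusted p = 0.0009, but adjusted p = 0.35 with an estimated correlation), with Ern2 up 1.34 ± 0.19. Crypt and stem cell genes stood higher with 0 of 17 called in limma, 1 adjusted over the list alone and 5 at an unadjusted p of 0.05 (median 0.29, adjusted p = 0.0045, but adjusted p = 0.51 with an estimated correlation). In limma 0 of 11 tuft markers passed by either adjustment and 5 were lower at an unadjusted p of 0.05 (median -0.61, adjusted p = 0.0007, but adjusted p = 0.37 with an estimated correlation). The T cell list (median -0.32, adjusted p = 0.023, but adjusted p = 0.59 with an estimated correlation) was not called without Cdx2 knockout 1 (adjusted p = 0.223) or double knockout 3 (0.495). The stromal list (median -0.31, adjusted p = 0.021, but adjusted p = 0.32 with an estimated correlation) was not called without Cdx2 knockout 3 (0.0505) or double knockout 1 (0.0644). Without Cdx2 knockout 1 the medians were -0.28 for the tuft, 0.22 for the goblet and -0.31 for the xenobiotic list, and without Cdx2 knockout 3 they were -1.03 for the tuft and 0.49 for the crypt list, all still called. In limma 0 T cell or stromal members passed by either adjustment, and 0 T cell and 3 stromal markers were lower at an unadjusted p of 0.05.

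In all, 519 genes were called between the labelled double and Cdx2 knockouts, 241 higher and 278 lower, 175 of them at least 2-fold. The count was 181 without Cdx2 knockout 1, 205 without Cdx2 knockout 2, 173 without double knockout 2, 151 without double knockout 3 and 337 without Hnf4a knockout 1 or 2. It was 1991 with array weights and 196 with only the groups compared in the fit. Without the 4 arrays of highest 18S signal only double knockout 1 and Cdx2 knockouts 1 and 2 remain of the groups compared. That fit cannot tell an effect of 18S signal from the loss of replicates. All 32 named calls kept their direction in it. Origin and genotype cannot be told apart in this contrast.

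Whether the effects of both losses add up on the log2 scale was tested with the interaction. Mal stood above the additive value by 4.02 ± 0.23 (SE, adjusted p = 3e-05), Cldn18 by 3.92 ± 0.39 (adjusted p = 0.002) and Tff2 by 3.80 ± 0.39 (adjusted p = 0.002). Saa1 (-2.95 ± 0.25, adjusted p = 0.00053) and Prss30 (-2.06 ± 0.25, adjusted p = 0.0069) stood below it. These 5 calls held whichever array was left out. Wfdc2 stood above by 3.53 ± 0.46 (adjusted p = 0.011, but 0.0624 without Hnf4a knockout 2). Tff2 averaged 8.35 in the controls, 10.17 in the Cdx2 group, 8.64 in the Hnf4a group and 14.26 in the double knockout. Gkn1 stood above by 4.48 ± 0.77 (adjusted p = 0.048), but was lost in 10 of 12 fits that each lacked 1 array (adjusted p = 0.0852 to 0.264) and with the replicate number as a block over 12 arrays (adjusted p = 0.0781). Its levels in the controls (6.64) and the Hnf4a group (6.48) lay below the 30th percentile (6.75), as did those of Saa1 in the controls (5.53), the Cdx2 group (5.02) and the double knockout (4.85). Cldn18 lay just above that percentile, at 6.85 in the controls and 6.80 in the Hnf4a group. Interactions of genes at such levels are differences of signals that a floor can produce. The floor of a feature can also lie well above that percentile, so a floor is not excluded for Tff2 either. Gastric genes stood above additivity in 4 of 16 cases, 7 adjusted over the list alone (median 1.39, adjusted p = 4e-11, and adjusted p = 0.0017 with an estimated correlation). The gastric median was 0.90 without double knockout 1, still called.

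Antimicrobial and MHC class II genes stood below additivity in 2 of 16 cases, 3 adjusted over the list alone (median -1.17, adjusted p = 1.3e-05, and adjusted p = 0.0161 with an estimated correlation), and -0.76 and -0.53 without Cdx2 knockouts 2 and 3, both still called. Stromal markers had 0 of 7 members called in limma, 1 below adjusted over the list alone and 2 at an unadjusted p of 0.05 (median -0.36, adjusted p = 0.00029, and adjusted p = 0.0309 with an estimated correlation). Myeloid markers stood below additivity as a list, with 0 of 12 called in limma, 10 adjusted over the list alone and 11 at an unadjusted p of 0.05 (median -1.26, adjusted p = 4e-11, but adjusted p = 0.20 with an estimated correlation and 0.122 by fry). The list stood at 1.78 in Hnf4a knockout 1 and 0.42 in Hnf4a knockout 2, and its median interaction was -0.64 without the former and -1.89 without the latter. In all, 32 genes were called, 19 above and 13 below additivity, and 983 passed an unadjusted p of 0.05. Without control 4, the only array of its origin, the count was 25, 14 above and 11 below. Without the 4 arrays of highest 18S signal only double knockout 1 and Hnf4a knockout 2 remain of their groups. That fit cannot tell an effect of 18S signal from the loss of replicates. All 10 named calls kept their direction in it. The count was 20 without control 2, 12 and 18 without Cdx2 knockouts 1 and 2, and 17 and 18 without double knockouts 2 and 3. It was lower too without either Hnf4a knockout array, which leaves 1 in that group. With array weights it was 84, and with control 4 as the only control 10.

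**Figure D4:**
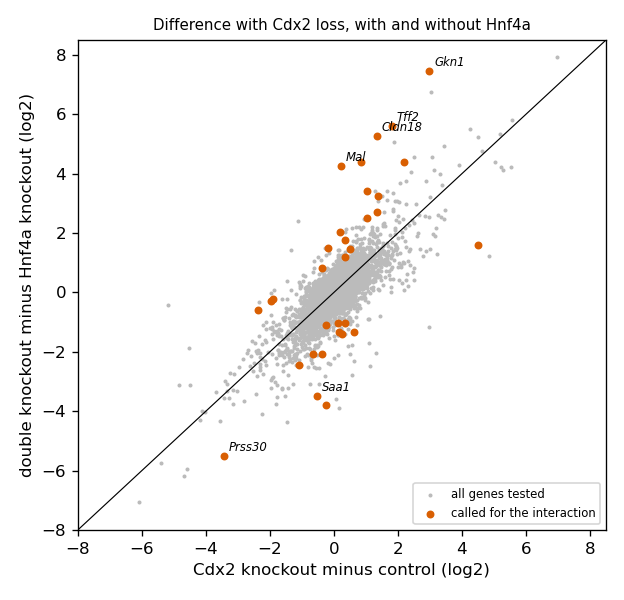
Log2 difference of each gene between the labelled Cdx2 knockout and control arrays (horizontal) and between the labelled double and Hnf4a knockout arrays (vertical), with a line where both are equal. All 11817 genes are grey and the 32 called for the interaction orange; the correlation over genes is 0.763.

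The effect of Cdx2 loss with and without Hnf4a was compared over contrasts that share no arrays. In both, 396 genes were called higher, Ttr and Sult1c2 among them, and 369 lower, such as Dnase1 and Reg3a, and 2 were called in opposite directions; independent lists would share 42.2 and 36.8. The correlation over genes was 0.763, genes not being independent replicates.

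Between the labelled Cdx2 knockout and the Hnf4a knockout, both against the same controls, 11 genes were called higher in both, 16 lower in both and 10 in opposite directions, where independent lists would share 2.39 and 1.98. The correlation over genes was 0.175, against 0.377 for simulated unchanged groups that share these controls, and the covariance 0.0299 against a simulated 0.0174. With the controls split so that the comparisons shared none, 12 to 32 genes were called in the same direction and the covariance was -0.0155 to 0.0223. The shared count of 27 was 16 without control 2, 45 without control 3, 6 and 11 without Hnf4a knockouts 1 and 2, and 17 without double knockout 2, and 144 with array weights. Between the labelled Cdx2 and double knockouts 551 genes were called higher in both, 591 lower in both and 6 in opposite directions, against 89.3 and 82.7 for independent lists; the covariance was 0.271 against a simulated 0.0174, and 0.216 to 0.264 with split controls. Of the 2804 genes called for the double knockout, 1148 were also called for the labelled Cdx2 knockout, 55 also for the Hnf4a knockout and 1633 for neither, of which 10 were called for the interaction.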

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

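Of the tests here, those of swapped arrays, of exchanged groups and of origin as the source of the Cdx2 signal were chosen only after the result was seen, as were the fit without the arrays of highest 18S signal and the rules for reading the tests of the array floor, of origin behind the gastric genes and of the splits of control and Cdx2 knockout arrays.

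Gastric genes stood above additivity in the labelled double knockout, with a list median of 1.39; among the genes called were Gkn1 (4.48), Mal (4.02), Cldn18 (3.92), Tff2 (3.80) and Wfdc2 (3.53), Mal and Wfdc2 not being on the gastric list. Control 4, the only array of its origin, was argued against as the cause, since without it, which is all that the origin as a fixed block changes here, the median was 1.44 and 3 gastric genes were called; between the other origins an additive effect cancels by design, and an origin that alters the response to loss of Cdx2 cannot be told apart. Stomach tissue in the samples was tested with the parietal and chief cell transcripts Atp4a, Atp4b, Cblif and Pgc. They rose by a mean of 1.74 against 6.63 for Gkn1, Gkn2 and Tff2. That met the bound written beforehand against this cause, but the bound cannot decide. Pgc (3.24), Atp4a (2.36) and Cblif (1.32) did rise. Their control levels of 7.54, 7.37 and 7.29 lay where a floor may hide part of a rise. Muc5ac (0.16) and Atp4b (0.05), which lowers the mean, may sit on features that do not respond. An array floor that hides an effect of Hnf4a loss alone could not be excluded. Of the 4 gastric genes called, 3 had control and Hnf4a knockout means above the 30th percentile (6.75), the bound written beforehand against a floor, but that bound was wrong because Muc5ac and Atp4b, called in no contrast, averaged 7.59 and 8.45 in the controls, so the floor of a feature can lie well above that percentile; a joint action of both losses stays a hypothesis.

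Signal of Cdx2 was higher, not lower, in the arrays labelled Cdx2 knockout. A swap of single arrays between control and Cdx2 knockout was argued against, as 0 of the 12 arrays correlated best with an array of the opposite Cdx2 label. Origin of the arrays was argued against too, since over the 6 arrays of 1 origin the difference was 0.68 with an SE of 0.26. An exchange of the control and Cdx2 knockout labels as whole groups in 1 origin was argued against, unless loss of Cdx2 acts in opposite ways with and without Hnf4a, by 765 genes called in the same direction and 2 in opposite ones in contrasts that share no arrays, while an exchange in both origins was not tested. Probes outside the deleted part, with more transcript made from the altered gene, may give the same signal, for which no probe positions were used here.

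Loss of Hnf4a called 71 genes and labelled loss of Cdx2 1451. A group of 2 arrays was argued against as the whole cause, since 2 of the 3 Cdx2 knockout arrays still called at least 1015 genes. Effects of the same size under a wider spread were argued against as well, the SD of log2 differences over genes, less the sampling variance, being 0.23 for Hnf4a and 0.48 for Cdx2. A smaller response to loss of Hnf4a alone, a residual Hnf4a protein 3 to 4 days after tamoxifen, and the other origin of these arrays could each contribute and were not told apart.

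Other splits of the arrays tested whether chance can be excluded. Of 35 splits of the control and Cdx2 knockout arrays, only the real 1 called as many as 1451 genes, the highest of the others being 183. If the numbers pair these arrays, as was assumed, only the 8 splits that part all 3 pairs compare with it. These are too few for a share under 0.05, and the highest other of these was 18. The remaining splits put both arrays of a pair in 1 group. Of 35 splits for the double knockout against control only the real 1 reached 2804, the highest of the others being 1517. That share, the smallest that 35 splits can give, argues against a random grouping of these arrays. Origin parts the arrays in the same way as genotype, so the splits cannot tell which of them is the cause. The double against the Cdx2 knockout has only 10 splits, too few for a share under 0.05, and the real 1 called 519 genes and the highest other 1.

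Below additivity were Dio1 (-3.57), Saa1 (-2.95), Angptl4 (-2.91), Prss30 (-2.06) and C2 (-1.96), and the interaction called 32 genes in all. Of the genes named, Gkn1, Dio1, Angptl4 and C2 were lost without any 1 of 10, 9, 8 and 4 arrays (adjusted p = 0.0852 to 0.264, 0.0701 to 0.237, 0.0784 to 0.247 and 0.0582 to 0.134). Wfdc2 was lost without Hnf4a knockout 2 (0.0624). The replicate number was also set as a block over 12 arrays, although it was taken to pair only control with Cdx2 knockout arrays. With this block Gkn1 (adjusted p = 0.0781) and C2 (0.0825) were not called. Nor were the sugar list (median -0.07, adjusted p = 0.383) and the tuft list (-0.15, adjusted p = 0.287). Gkn2 was newly called (4.10, adjusted p = 0.0315). Camera, which sets a list against the other genes, called lists with medians away from 0 beside the gastric list: brush border genes (-0.36), sugar, amino acid and peptide transport (-0.51), mineral and vitamin uptake (-0.63), ileal and colonic genes (-0.50), tuft markers (-0.48), cell cycle genes (0.65), cholesterol synthesis (-0.31), antimicrobial and MHC class II genes (-1.17), interferon response (-0.46), myeloid markers (-1.26) and stromal markers (-0.36). In limma 0 members of the brush border, sugar, mineral, ileal, tuft, cell cycle, cholesterol and interferon lists were called, against 2, 2, 6, 4, 0, 0, 3 and 0 at an unadjusted p of 0.05, and fry, which tests against no change, called none of these lists (adjusted p = 0.162 to 0.63). With an estimated correlation only the gastric, antimicrobial and stromal lists were called, with adjusted p = 0.00168, 0.0161 and 0.0309, and fry called the same 3. Without control 4 the sugar, ileal and tuft lists were not called (medians -0.23, -0.35 and -0.34, adjusted p = 0.18, 0.0577 and 0.0525), the tuft list also not without any 1 of 5 other arrays (0.0562 to 0.299). The interferon list was not called without Cdx2 knockout 3 (0.0881) or double knockout 2 (0.269). Without the 4 arrays of highest 18S signal its median was 0.44, in the opposite direction. That fit keeps only double knockout 1 and Hnf4a knockout 2 of their groups. The mean of the list lay 2.11 above the control mean in double knockout 1, against 0.21 and 0.96 in double knockouts 2 and 3. The turn may therefore rest on 1 array.

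Single control arrays stood apart for 3 of 71 values checked, where chance gives about 1 in 20. They were the mean of the mineral and vitamin uptake list in control 3 (-0.36 from the control mean), Tmigd1 in control 1 (11.12) and Gkn1 in control 4 (6.83).

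Control features of 18S ribosomal RNA, used in no comparison, exceeded every control array in Cdx2 knockouts 2 (8.37) and 3 (10.64), Hnf4a knockouts 1 (9.30) and 2 (8.93) and double knockouts 2 (9.02) and 3 (9.61). Among 1300 tested features without a symbol, 101 were called for the labelled Cdx2 knockout, 15 for the Hnf4a knockout and 203 for the double knockout against control.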

How the results depend on the processing

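The fits over the 6 arrays of 1 origin, the same with the replicate block, and the fit without the 4 arrays of highest 18S signal were chosen only after the result was seen. Of named genes over all alternatives 16144 values stayed on their side of the threshold. Of the others 793 were no longer called, 317 were newly called and 0 turned in direction. For lists these numbers were 3538, 129, 145 and 4. A turn was counted only for a value called in the fit over all arrays, in the alternative or in both. A value called in neither counted as staying, whatever its direction. Of 254 calls of named genes 107 held in every alternative. No count moved over 1.5 times with centring, renormalization, a stricter filter, the mean feature per gene or a trended and robust spread. Where a count moved the cause was not tested, except that stricter thresholds pass fewer genes and smaller sets of arrays leave fewer degrees of freedom.

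Genes called ranged, over fits that each left out 1 array, from 1015 to 1442 for Cdx2 against control, 10 to 94 for Hnf4a, 1877 to 3110 for the double knockout, 493 to 1401 for double against Hnf4a, 151 to 657 for double against Cdx2, 9 to 44 for the interaction, and 6 to 45 for genes shared by Cdx2 and Hnf4a. Lists called ranged, in the same order of contrasts, 9 to 11, 7 to 13, 10 to 12, 10 to 12, 12 to 15 and 9 to 15. Where 1 array is left in an arm it is assumed to vary like the other groups.

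Array weights gave 489 genes for Hnf4a, 3186 for double against Hnf4a, 1991 for double against Cdx2, 84 for the interaction, 144 shared and 13 lists for Hnf4a; without the filter Hnf4a had 12 lists. Fitting only the groups compared gave 955 for Cdx2, 41 for Hnf4a and 196 for double against Cdx2; for the interaction this cannot differ. Control 4 as the only control gave 619 for Cdx2, 25 for Hnf4a, 1282 for double, 10 for the interaction and 14 shared. A 2-fold minimum gave 503, 38, 847, 616 and 175 in the first 5 contrasts, and an adjusted p under 0.01 gave 689, 26, 1554, 640, 117 and, for the interaction, 10. With an estimated correlation 1, 0, 1, 2, 1 and 3 lists were called in the 6 contrasts, the 0 being camera's for Hnf4a, where 2 lists had an unadjusted p under 0.05. Fry called 1 list for Hnf4a, 4 for double against Cdx2 and 3 for the interaction. The 6 arrays of 1 origin gave 708 genes for Cdx2. Without the 4 arrays of highest 18S signal the counts were 743, 6, 624, 171, 38 and 1, with 4 shared. The 6 ways to split the controls gave 13, 13, 13, 17, 12 and 32 shared.

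The replicate block over the groups compared gave 164 genes for Hnf4a, 1795 for double, 199 for double against Cdx2, 13 lists for Hnf4a and 57 shared; over 12 arrays it gave 142 for Hnf4a, 784 for double against Cdx2, 15 lists for Hnf4a and 53 shared. The numbers were taken to pair only control with Cdx2 arrays. Same-number correlations were -0.24 for control and Hnf4a, 0.05, 0.09 and 0.09 for control and double, -0.12 for Hnf4a and double, and 0.14, -0.01 and -0.05 for Cdx2 and double, and not every array correlated best with its own number. For Cdx2 against control the block gave 1246 genes and, beside Cdx2 and the sugar list, newly called Agr2, Ang4, Ctrb1, Herpud1, Mptx1 and Siglecf and no longer called Cyp1a1 (adjusted p = 0.0797), Hyou1 (0.112) and Tpsg1 (0.0537); it changed no other call of a gene or list reported here.

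Among lists called over 12 arrays or in the alternative, directions differed from camera's over 12 arrays in 4 cases. For double against Cdx2 the interferon list, not called over 12 arrays, was called higher without double knockout 2 (0.48) and without the 4 arrays of highest 18S signal (1.19), but lower without double knockout 1 (-0.51). For the interaction it was called above additivity without those 4 arrays (0.44). Leaving them out keeps only double knockout 1 of its group, the array in which this list stood highest, so both turns may rest on that array. Fry called the transcription factor list, which holds both targeted genes, lower for double against control despite a median of 0.25. Lists were not run with the origin as a random block, which camera does not take.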

Other observations

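The test of Hnf4g here was chosen only after the result was seen, and the genes in the next paragraph were chosen after their values were seen.

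Besides the genes named for the interaction, others stood above additivity in the labelled double knockout. Vsig2 averaged 8.37 in the controls, 9.39 in the Cdx2 group, 8.45 in the Hnf4a group and 11.88 in the double knockout (interaction 2.41 ± 0.19 SE, adjusted p = 0.000369), and the gastric protease Ctse 8.45, 9.83, 8.81 and 12.07 (1.87 ± 0.20, adjusted p = 0.0023). The nuclear receptor Pparg (1.37 ± 0.24, adjusted p = 0.049) and the glycolytic enzyme Hk1 (1.46 ± 0.25, adjusted p = 0.0424) were also called. Against the controls Rdh7 differed by 2.19 in the Cdx2 group, -3.32 in the Hnf4a group and 1.08 in the double knockout (interaction 2.21 ± 0.30, adjusted p = 0.0137). Below additivity, Cldn15, a claudin of the small intestine, averaged 13.35, 12.26, 12.83 and 10.38 (-1.35 ± 0.22, adjusted p = 0.0322). How these genes fare when 1 array is left out was not run.

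Loss of Hnf4a called 519 genes where Cdx2 was also lost and 71 where it was not, while the interaction called 32. A hypothesis is that Hnf4g, a receptor closely related to Hnf4a, may replace it less where Cdx2 is lost. Hnf4g was lower by 1.71 (log2, adjusted p = 0.0165) in the labelled Cdx2 knockout and by 1.36 (adjusted p = 0.0282) in the double knockout than in the controls, as the hypothesis needs. Over the 6 arrays of 1 origin the first difference was -1.50, not called without a block (adjusted p = 0.126) but called with the replicate block (0.0129). The call was lost with only the groups compared (0.053), with control 4 as the only control and in the fit without the 4 arrays of highest 18S signal (-1.19, adjusted p = 0.0806). The interaction of Hnf4g itself was -0.04. Both counts also rest on different numbers of arrays and on contrasts in which origin and genotype cannot be told apart, so the test does not show a replacement.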
